A study of Homo sapiens with 18 samples.

How the data were processed

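Gene expression was measured by RNA sequencing in MDA-MB-231 cells, an established human triple-negative breast cancer line. The 18 libraries form 6 groups of 3, all with the same batch label. Wild-type cells and cells with a TRIM27 knockout were each sequenced without treatment, after olaparib (2 µM, 24 h) and after an siRNA against PARP1 (labelled 100 pM, 48 h). Per the labels' protocols, RNA was extracted with TRIzol and 1 µg went into libraries primed with oligo(dT) beads. The same protocols speak of DMSO and of a non-targeting siRNA, but no library used here is labelled as having received either, so the untreated cells of each genotype were the only controls.

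Both tables used here hold FPKM values (fragment counts divided by transcript length and library size) as deposited by the authors, 1 with a value per gene and 1 with a value per transcript. The submitters' processing notes name fastp 0.23.2, HISAT2 2.2.1, featureCounts 2.0.3, StringTie 2.2.1, DESeq2 1.38.3 and the GRCh38 build. Which of these tools made the FPKM values, with which annotation release and with which strand setting, is not given in the sources used here. The gene table lists 62830 genes, of which 61860 have Ensembl identifiers and 970 are unnamed loci assembled by the authors. The unnamed loci held 43.41 to 49.77% of each library's summed FPKM. This share was lower in the treated groups. Its mean was 49.3% in wild-type and 48.75% in knockout cells without treatment, 46.8% and 45.1% under olaparib, and 45.4% and 43.9% under siPARP1. Named genes therefore held a larger part of the total in treated cells. Symbols were found for 61757 identifiers, and positions for 58308 in GENCODE 29 on GRCh38. The transcript table lists 251074 transcripts. Its sums lay within 1% of the gene value for 10961 of the 13399 genes compared. Why the others differed was not tested, and as 202952 of the listed transcripts matched a gene in GENCODE 29, the sums served only as an alternative.

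Read counts were not used here, so the absolute depth of the libraries is unknown. Summed FPKM ran from 812699 to 910313 per library. Low genes took values in steps of what 1 read is worth, and the ratios of these steps put the libraries' depth at 0.749 to 1.237 times that of wild-type library 1. An FPKM of exactly 0 is described as listed at 0, with each library's value. The values are shares of a library, and a change in abundant transcripts moves the rest.

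Genes with at least 1 FPKM in at least 3 of the 18 libraries were kept, which left 15764. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in a single fit of all 6 groups with a mean-dependent prior variance, 12 residual degrees of freedom and a prior of 2.06. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called changed at an adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors of log2 changes are standard errors (SE) and errors of FPKM are standard deviations (SD) over 3 libraries. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The 9 comparisons were knockout against wild type without treatment, under olaparib and under siPARP1, each treatment against no treatment in each genotype, and the interaction of each treatment with genotype. PAX6 fell below the filter, and its values come from the same fit over 41488 genes with no filter.

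The groups, tests, gene lists and most alternatives were fixed before the data were examined. The 24 lists covered mesenchymal and epithelial markers, invasion proteases and their inhibitors, adhesion and migration, interferon-stimulated genes, NF-kB targets and cytokines, p53 targets, DNA repair, the PARP family, G1/S and G2/M cell cycle genes, the integrated stress response, the endoplasmic reticulum (ER) stress response, cholesterol synthesis, hypoxia and glycolysis, TGF-beta response genes, immediate early genes, transcripts encoded in mitochondria, ribosomal proteins, replication-dependent histones, the WASH and retromer complexes, and luminal, leukocyte and neural markers. Lists were tested with camera in limma at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Members were counted by their adjusted p over all genes, and again adjusted over the list alone.

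Genes named by rule were TRIM27, PARP1 and PAX6, and the 8 largest rises and 8 largest falls in each of the 3 main comparisons (4 and 4 in the others). These had to have a symbol, a mean of at least 5 FPKM in the higher group, an adjusted p under 0.05 and no overlap between the libraries of the groups. Interactions gave 4 and 4 genes with a mean of at least 5 FPKM in the highest of their groups. Up to 4 members with the smallest p of each list that passed in the 3 main comparisons were added. The text gives some of these members as examples, and values of the other genes that the rule named are not reported here.

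The fit was tested on simulated data with the real means and spreads and 200 changed genes among 15764. For knockout against wild type it recovered 64.6% of genes changed 1.5-fold, 89.8% of those changed 2-fold and 98.3% of those changed 4-fold, and 6.82% of its calls were unchanged genes. For olaparib in wild-type cells these shares were 71.9%, 86.3% and 98.6%, with 3.89% of calls unchanged, and for siPARP1 in wild-type cells 67.2%, 86.2% and 95.6%, with 6.21%. For the olaparib interaction they were 53.0%, 69.2% and 94.2%, with 8.23%, and for the siPARP1 interaction 49.4%, 74.6% and 89.1%, with 5.44%.

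Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, sums of the transcript table, a robust prior variance without trend, a fit of only the groups compared, a replicate block, and each library left out in turn. Scaling on protein-coding genes, leaving out the assembled loci and removing bin medians were added after the data had been seen, as was leaving out each library for the lists and overlaps. Removing bin medians took the median difference of knockout and wild type in each 10 Mb bin with at least 10 protein-coding genes of at least 5 FPKM, over all chromosomes and averaged over the 3 backgrounds, out of the knockout libraries. Overlaps between comparisons that share control libraries were set against 50 simulated sets of unchanged groups. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.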

Results

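The transcriptome of MDA-MB-231 cells, a mesenchymal-like breast cancer line, was measured in wild-type cells and in cells in which TRIM27, a ubiquitin ligase of the tripartite motif family, had been knocked out. Both genotypes were sequenced without treatment, after olaparib, an inhibitor of the DNA repair enzymes PARP1 and PARP2, and after siRNA against PARP1 (siPARP1). Each of the 6 groups had 3 libraries. The design concerns a TRIM27, PARP1 and PAX6 axis in invasion and metastasis. Between 14183 and 14584 genes reached 1 FPKM per library, and libraries of a group correlated across genes at 0.9822 to 0.9882, against 0.9391 to 0.9819 between groups. Transcripts of the mitochondrial genome made up 21.2 ± 1.33% of the FPKM of annotated genes in untreated wild-type cells (SD, n = 3), 19.7 ± 0.63% in untreated knockout cells, 24.8 ± 0.805% and 24.5 ± 0.905% under olaparib, and 25.8 ± 0.337% and 27.6 ± 0.517% under siPARP1.

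TRIM27 RNA was lower, though still present, in the knockout libraries. TRIM27 (ENSG00000204713, GRCh38 chromosome 6, 28903002 to 28923989) measured 1.45 ± 0.243 FPKM in wild-type cells and 0.623 ± 0.066 FPKM in knockout cells (SD, n = 3), which is 43.1% of the wild-type level. The log2 change was -0.59 (SE 0.096, limma adjusted p = 0.000538), and it was -0.55 under olaparib (adjusted p = 0.00132) and -0.56 under siPARP1 (adjusted p = 0.000775). An RNA level does not show whether protein was made. Under siPARP1, TRIM27 rose by a log2 of 0.26 in wild-type cells (adjusted p = 0.0333), to 1.95 ± 0.437 FPKM, and by 0.29 in knockout cells (adjusted p = 0.0182), to 0.99 ± 0.048 FPKM. The wild-type rise passed neither with median-of-ratios scaling (0.21, adjusted p = 0.0904) nor without untreated library 1 (0.18, adjusted p = 0.155) or siPARP1 library 3 (0.15, adjusted p = 0.176). The knockout rise ended without untreated library 2 (adjusted p = 0.0633) or siPARP1 library 3 (adjusted p = 0.0536).

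PARP1, the main enzyme of poly(ADP-ribose) synthesis at DNA breaks, followed the siRNA label (ENSG00000143799, chromosome 1, 226360691 to 226408079). It measured 56.2 ± 2.57 FPKM in wild-type and 55.2 ± 3.70 FPKM in knockout cells, a difference that did not pass (adjusted p = 0.85). With siPARP1 it fell to 10.7 ± 0.883 FPKM in wild-type cells, 19.1% of the untreated level (log2 -2.29, adjusted p = 3.63e-12), and to 9.25 ± 0.472 FPKM in knockout cells, 16.8% (log2 -2.45, adjusted p = 1.37e-12). Olaparib also lowered PARP1 RNA, to 38.8 ± 2.75 FPKM in wild-type cells (log2 -0.52, SE 0.068, adjusted p = 2.15e-05) and to 40.1 ± 1.23 FPKM in knockout cells (log2 -0.45, adjusted p = 7.99e-05). Sums of the listed transcripts did not pass under olaparib (adjusted p = 0.109 and 0.733) or for siPARP1 in knockout cells (adjusted p = 0.206). Those sums held only 14.3 of the 56.2 FPKM in untreated wild-type cells and 8.77 of the 55.2 FPKM in untreated knockout cells, so they miss most of the gene's value. PAX6, a paired-box transcription factor of eye and brain development (ENSG00000007372, chromosome 11, 31784779 to 31818062), stayed near 1 FPKM or below in every group. It measured 0.411 ± 0.085 FPKM in wild-type and 1.03 ± 0.132 FPKM in knockout cells, 249.8% of the wild-type level (log2 0.52, SE 0.119, adjusted p = 0.0142). In knockout cells PAX6 fell to 0.239 ± 0.174 FPKM under olaparib (log2 -0.72, adjusted p = 0.000487) and to 0.504 ± 0.169 FPKM under siPARP1 (log2 -0.43, adjusted p = 0.0151), the latter lost without untreated library 2 or siPARP1 library 1 or 2. Knockout and wild type did not differ past the threshold under olaparib (adjusted p = 0.97) or siPARP1 (adjusted p = 0.873), and neither interaction passed (adjusted p = 0.314 and 0.301). The rise in knockout cells was lost with a pseudocount of 0.1 (log2 1.15, adjusted p = 0.0926), without wild-type library 3 (adjusted p = 0.0625) and without knockout library 2 (adjusted p = 0.062).

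**Figure D1:**
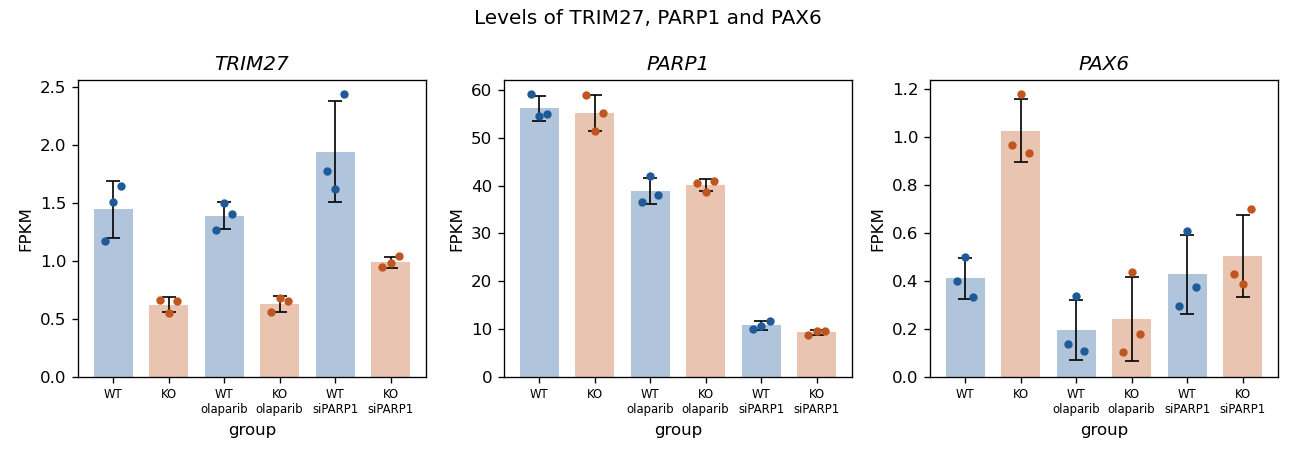
FPKM of TRIM27, PARP1 and PAX6 in the 6 groups (bars, mean of 3 libraries; error bars, SD; points, libraries). PARP1 lies near 56.2 FPKM in untreated wild-type cells and near 10.7 FPKM after siPARP1, while PAX6 reaches 1.03 FPKM only as the mean of untreated knockout cells.

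Knockout and wild-type cells were compared without treatment first. TIMP3, a tissue inhibitor of metalloproteinases (chromosome 22, 32801701 to 32863043), fell from 72.6 ± 0.56 to 3.54 ± 0.263 FPKM (log2 -4.02, SE 0.04, adjusted p = 3.05e-17). The neutrophil chemokine CXCL8 (chromosome 4, 73740506 to 73743716) fell from 23.0 ± 0.1 to 1.35 ± 0.249 FPKM (log2 -3.35, adjusted p = 1.72e-13), and CXCL1 from 43.4 ± 1.42 to 6.84 ± 0.168 FPKM (log2 -2.50, adjusted p = 1.98e-14). SERPINB2, an inhibitor of plasminogen activators, fell from 11.8 ± 0.142 to 0.149 ± 0.079 FPKM, the ubiquitin hydrolase UCHL1 from 31.4 ± 1.27 to 0.143 ± 0.072 FPKM, and the long noncoding RNA LNCAROD from 33.1 ± 0.684 to 0.195 ± 0.136 FPKM. SNRPN fell from 5.16 FPKM and was listed at 0, 0.074 and 0 in the knockout libraries. The membrane protein gene EMP1 fell by 2.07 (SE 0.423, adjusted p = 0.00288), though its wild-type libraries were uneven, at 141.6, 44.1 and 142.0 FPKM, and it lies in a segment of chromosome 12 with a median of -0.28.

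Gelatinase A, MMP2 (chromosome 16, 55389700 to 55506691), rose in the same cells from 1.45 ± 0.211 to 7.02 ± 0.199 FPKM (log2 1.71, SE 0.066, adjusted p = 3.99e-10), and a membrane-type metalloproteinase, MMP24, from 8.38 to 23.4 FPKM. PADI2, which converts arginine to citrulline in proteins, rose from 2.78 ± 0.664 to 15.3 ± 0.96 FPKM (log2 2.12, adjusted p = 2.28e-08). The other large rises were CHAC1, a glutathione-degrading enzyme induced by ATF4, from 4.69 to 15.5 FPKM, MGARP from 4.10 to 13.9, the hypoxia-inducible ANKRD37 from 5.01 to 15.4, EPB41L4B from 4.96 to 14.3 and the retinol dehydrogenase RDH10 from 5.28 to 13.7. In all, 1510 genes were higher and 1717 lower in knockout cells, 52 and 100 of them by at least 2-fold. Higher genes made up 46.8% of the calls, and 59.0% after rescaling to TPM. Genes in 8 chromosome segments that shifted together in knockout cells were 10.9% of the genes tested and 19.6% of the calls.

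**Figure D2:**
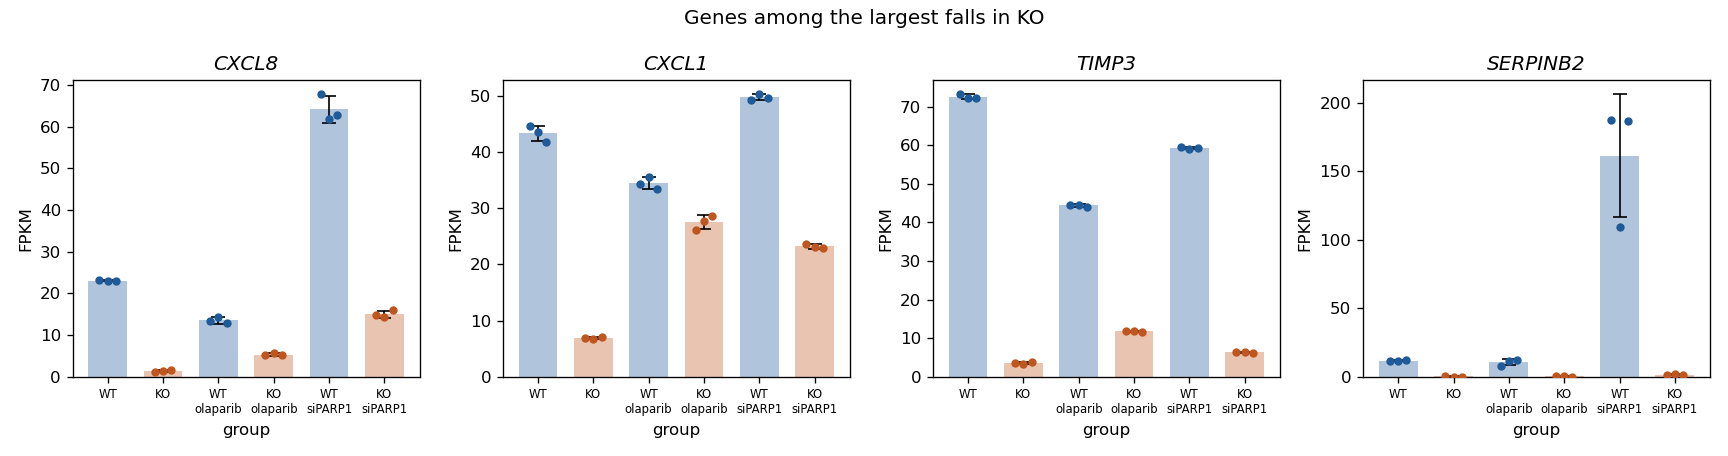
FPKM of CXCL8, CXCL1, TIMP3 and SERPINB2 in the 6 groups (bars, mean of 3 libraries; error bars, SD; points, libraries). CXCL1 falls from 43.4 to 6.84 FPKM between untreated wild-type and knockout cells and lies at 27.5 FPKM in knockout cells under olaparib, while SERPINB2 reaches 161 FPKM only in wild-type cells under siPARP1.

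Among the lists, targets of NF-kB fell together in knockout cells. Of 25 measured, 17 fell, 1 rose and 7 were not past the threshold (19 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.54 (camera adjusted p = 2.94e-14). IL1A, in a segment of chromosome 2 with a median of -0.27, fell from 31.9 to 7.21 FPKM and CXCL2 from 14.5 to 3.06 FPKM. Chaperones and folding enzymes of the ER stress response fell in 10 of 26 and rose in 3 (12 and 3 adjusted over the list alone, adjusted p = 0.00051), with HSPA5 down from 233 to 152 FPKM and DNAJB9 from 15.6 to 6.40 FPKM. HSPA5 and DNAJB9 lie in segments of chromosomes 9 and 7 whose medians were -0.22 and -0.18, and with the medians of 10 Mb bins removed over all chromosomes they changed by -0.37 and -0.99. The transcript sums of HSPA5 gave 1.499 (adjusted p = 0.657). The fall of the ER stress list was limited to untreated cells, as it did not pass under olaparib and was higher in knockout cells under siPARP1. HSPA5 libraries lay at 86.5 to 90.7 FPKM in wild-type and 87.5 to 91.5 FPKM in knockout cells under olaparib. Under siPARP1 they lay at 169.2 to 174.5 and 166.0 to 172.7 FPKM. G1/S genes fell in 11 of 37 and rose in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00132), among them PCNA, the sliding clamp of replication, from 109 to 79.7 FPKM, and the cyclin CCNE1 by 0.43. PCNA lies in a segment of chromosome 20, and changed by -0.18 with bin medians removed, against -0.45. G2/M genes fell in 5 of 40 and 35 were not past the threshold, with 4 fallen adjusted over the list alone, a median of 0.02, a mean of -0.006 and a downward test (adjusted p = 0.989). Immediate early genes fell in 10 of 25 and rose in 3 (11 and 3 adjusted over the list alone, adjusted p = 0.00417). The heat shock genes HSPA1A and HSPA1B, near-identical copies that share reads, fell by 0.97 and 0.99 and FOS by 1.09, whereas JUN rose by 0.60. Mitochondrial transcripts fell in 8 of 13, also adjusted over the list alone (adjusted p = 7.64e-05, but adjusted p = 0.254 with an estimated correlation), for instance MT-CYB by 0.48 and MT-ATP6 by 0.51.

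Hypoxia and glycolysis genes rose in 14 of 32 and fell in 2 in knockout cells (15 and 2 adjusted over the list alone, median 0.20, adjusted p = 5.29e-05). The glycolytic enzyme PGK1 rose from 100.5 to 149 FPKM and the mitophagy receptors BNIP3 and BNIP3L by 0.50 and 0.55. TGF-beta response genes rose in 13 of 28 and fell in 5 (14 and 6 adjusted over the list alone, adjusted p = 0.0398, and adjusted p = 0.0653 with an estimated correlation). The type IV collagens COL4A1 and COL4A2 rose by 0.69 and 0.87 and TGFB2 by 0.59, while THBS1 fell by 0.47. This call was lost without wild-type library 2 (adjusted p = 0.0691) or knockout library 1 (adjusted p = 0.0634). Targets of p53 rose in 9 of 27 and fell in 2 (9 and 4 adjusted over the list alone, adjusted p = 0.0386, and adjusted p = 0.0832 with an estimated correlation). The line carries mutant p53, and whether p53 itself drove these changes was not tested. The damage-induced phosphatase PPM1D rose by 0.54, a call lost with transcript sums (adjusted p = 0.106), the apoptosis gene PMAIP1 by 0.55 and the repair gene XPC by 0.50, and TIGAR fell by 0.43. The p53 call was lost without knockout library 2 (adjusted p = 0.101), and with bin medians removed (adjusted p = 0.224), where XPC, on chromosome 3, also ended (0.054, adjusted p = 0.5). TIGAR, on chromosome 12, changed by -0.13 in that alternative. The hypoxia, TGF-beta, p53 and mitochondrial lists passed for knockout against wild type only without treatment, and not under olaparib or siPARP1. PGK1 libraries, for instance, lay at 83.5 to 86.7 FPKM in wild-type and 86.3 to 88.1 FPKM in knockout cells under olaparib. Under siPARP1 they lay at 104.5 to 106.9 and 101.2 to 101.5 FPKM.

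The mesenchymal, epithelial, adhesion and invasion protease lists did not pass camera in knockout cells, although fry, which does not compare a list with other genes, gave adjusted p = 0.000544, 0.0024, 8.16e-05 and 1.87e-06. Of 23 mesenchymal markers 9 rose and 3 fell (9 and 5 adjusted over the list alone, median 0.15, camera adjusted p = 0.0793). With bin medians removed, an alternative chosen after the data had been seen, the mesenchymal median was 0.24 (adjusted p = 0.00618), and the epithelial and adhesion lists passed too (adjusted p = 0.0151 and 0.00744). The adhesion list also passed with a pseudocount of 0.1 (adjusted p = 0.0489), and without wild-type library 3 (adjusted p = 0.034) or knockout library 2 (adjusted p = 0.048), and the epithelial list without wild-type library 3 (adjusted p = 0.0474). Chosen after their values were seen, the transcription factor SNAI2 rose from 9.91 to 16.9 FPKM and fibronectin, FN1, from 363 to 508 FPKM, VIM fell by 0.16, and ZEB1 did not pass (0.17, adjusted p = 0.774). Epithelial markers rose in 6 of 13 and fell in 2 (7 and 3 adjusted over the list alone, adjusted p = 0.0654), adhesion and migration genes rose in 7 of 33 and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0556), and luminal markers rose in 3 of 8 (3, and 1 fallen, adjusted over the list alone, adjusted p = 0.0707). Invasion proteases and their inhibitors rose in 7 of 24 and fell in 5, also adjusted over the list alone, with a median of 0.034, a mean of -0.062 and an upward test (adjusted p = 0.44). Interferon-stimulated genes fell in 9 of 33 and rose in 3 (10 and 3 adjusted over the list alone, adjusted p = 0.114). Integrated stress response genes rose in 8 of 31 and fell in 2 (8 and 4 adjusted over the list alone, adjusted p = 0.0793), and PARP family genes rose in 4 of 22 and fell in 4 (7 and 4 adjusted over the list alone, adjusted p = 0.139). Few members changed among ribosomal proteins (4 rose and 3 fell of 73, adjusted p = 0.327), cholesterol synthesis (1 and 3 of 24, adjusted p = 0.431), WASH and retromer subunits (1 and 2 of 17, adjusted p = 0.527), DNA repair (3 and 2 of 37, adjusted p = 0.989) and replication-dependent histones (1 and 1 of 14, adjusted p = 0.937). The counts adjusted over the list alone were 2 and 3 for ribosomal proteins, 3 and 1 for DNA repair and 0 and 0 for histones, and the same as over all genes for the cholesterol and WASH lists. Of 3 neural markers 1 fell (1, and 1 risen, adjusted over the list alone, adjusted p = 0.937), and neither of 2 leukocyte markers passed, also adjusted over the list alone (adjusted p = 0.967).

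Olaparib was compared with no treatment in wild-type cells to give the response to inhibited PARP. The immediate early gene FOS rose from 3.93 ± 0.171 to 102 ± 2.74 FPKM (log2 4.39, SE 0.084, adjusted p = 4.94e-14). Histone genes followed, with H2BC11 up from 1.76 to 30.9 FPKM, H2AC18 from 3.76 to 44.6, H2AC19 from 3.72 to 43.1, H2BC8 from 3.61 to 41.9, H4C15 from 0.746 to 13.7 and H4C14 from 0.934 to 14.9. Copies of a histone gene share reads, so the split between them is uncertain. The stearoyl-CoA desaturase SCD (chromosome 10, 100347124 to 100364834) fell from 257 ± 2.43 to 59.6 ± 0.797 FPKM (log2 -2.09, SE 0.03, adjusted p = 2.55e-15). DDIT4, an inhibitor of mTORC1, fell from 53.7 to 9.19 FPKM, asparagine synthetase, ASNS, from 91.7 to 23.3, the lamin LMNB1 from 67.9 to 16.8, the replication-associated protease FAM111B from 13.2 to 1.76 and the NKG2D ligand ULBP1 from 6.97 to 0.836. MIR137, a short locus inside a host transcript, rose from 0.084 to 8.31 FPKM. The falls of TOMM6 (log2 -4.22, SE 1.5, adjusted p = 0.0332) and HNRNPA1L2 (log2 -2.82, SE 0.882, adjusted p = 0.0175), which have near-identical copies, rest on uneven libraries. TOMM6 stood at 96.0, 102 and 0.374 FPKM in the wild-type libraries and HNRNPA1L2 at 1.66, 1.69 and 14.9 FPKM under olaparib. TOMM6 was lost without any of 5 of the 6 libraries, and HNRNPA1L2 without olaparib library 1 (adjusted p = 0.0704) or 2 (adjusted p = 0.07).

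In the lists, olaparib lowered cell cycle genes and raised p53 targets and histones. G1/S genes fell in 36 of 37 (37 adjusted over the list alone, median -1.07, camera adjusted p = 4.99e-24), among them the replicative helicase subunit MCM6 from 39.9 to 10.2 FPKM and FEN1 by 1.25. G2/M genes fell in 37 of 40 (38 adjusted over the list alone, median -0.80, adjusted p = 2.56e-24), with TOP2A down from 155 to 66.3 FPKM and CDK1 from 70.0 to 25.6 FPKM. DNA repair genes fell in 23 of 37 and rose in 4 (23 and 5 adjusted over the list alone, adjusted p = 7.81e-06), for instance the exonuclease EXO1 from 15.4 to 3.82 FPKM. Targets of p53 rose in 23 of 27 and fell in 1, also adjusted over the list alone (median 0.78, adjusted p = 5.73e-13). As the line carries mutant p53, these rises do not by themselves show p53 activity, which was not tested. MDM2 (chromosome 12, 68808176 to 68850686), a ubiquitin ligase, rose from 70.5 ± 2.41 to 241 ± 2.95 FPKM, the antiproliferative BTG2 from 8.76 to 27.99 FPKM and TP53INP1 by 1.23. All 14 measured histones rose (14 adjusted over the list alone, median 2.40, adjusted p = 5.73e-13), with H1-2 up from 16.8 ± 0.723 to 130 ± 5.76 FPKM. Most transcripts of this class end in a stem-loop without a poly(A) tail, which limits what oligo(dT) libraries say of their amount. Immediate early genes rose in 14 of 25 and fell in 4 (14 and 4 adjusted over the list alone, adjusted p = 0.000297), with EGR1 up from 5.97 to 52.1 FPKM. TGF-beta response genes rose in 21 of 28 and fell in 2, also adjusted over the list alone (adjusted p = 5.57e-07), including CCN2 from 72.4 to 179 FPKM and ID2 by 1.91.

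Metabolic and stress lists also changed under olaparib in wild-type cells. Integrated stress response genes fell in 25 of 31 and rose in 4, also adjusted over the list alone (median -0.83, adjusted p = 7.63e-13), with MTHFD2, a mitochondrial folate enzyme, down from 116 to 32.7 FPKM. Cholesterol synthesis fell in 19 of 24 and rose in 1 (20 and 1 adjusted over the list alone, adjusted p = 1.04e-11), for example SQLE by 1.22 and the regulator SREBF2 by 1.02. ER stress genes fell in 16 of 26 and rose in 2 (16 and 3 adjusted over the list alone, adjusted p = 3.39e-05), HSPA5 from 233 to 88.7 FPKM, though its transcript sums gave 0.91 (adjusted p = 0.738). Interferon-stimulated genes fell in 17 of 33 and rose in 5, also adjusted over the list alone (adjusted p = 0.000402), IFI44 by 1.46, although IFIT1 rose by 0.72. NF-kB targets fell in 15 of 25 and rose in 6, also adjusted over the list alone (adjusted p = 0.00269), ICAM1 by 0.88 and CXCL8 by 0.73. Hypoxia genes fell in 15 of 32 and rose in 6, also adjusted over the list alone (adjusted p = 0.0124, and adjusted p = 0.0584 with an estimated correlation), the hexokinase HK2 by 0.57. Mitochondrial transcripts rose in 9 of 13 (10 adjusted over the list alone, adjusted p = 0.000726, but adjusted p = 0.352 with an estimated correlation). Ribosomal proteins fell in 16 of 73 and rose in 3 (12 and 3 adjusted over the list alone, adjusted p = 0.00818, but adjusted p = 0.356 with an estimated correlation), RPL3 by 0.92. Mesenchymal markers did not pass as a list (7 rose and 5 fell, 9 and 5 adjusted over the list alone, adjusted p = 0.732), nor did adhesion genes, whose median of 0.004 and mean of 0.016 went with a downward test (adjusted p = 0.808). In all, 3932 genes were higher and 3219 lower with olaparib, 417 and 270 by at least 2-fold. Higher genes were 55.0% of the calls, and 47.7% with median-of-ratios scaling, which turns the majority. With no vehicle-treated group analysed here, the drug cannot be separated from its solvent and handling.

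Knockdown of PARP1 was compared with no treatment in wild-type cells to set its knockdown beside its inhibition. ANKRD1 (chromosome 10, 90912096 to 90921276), a target of YAP, rose from 64.0 ± 1.93 to 676 ± 13.6 FPKM (log2 3.38, SE 0.034, adjusted p = 2.86e-17). SERPINB2 rose from 11.8 ± 0.142 to 161 ± 45.0 FPKM (log2 3.62, SE 0.185), and ID3, a repressor of helix-loop-helix factors, from 1.43 to 11.2 FPKM. The arylacetamide deacetylase AADAC rose from 0.556 to 9.10 FPKM and the related pseudogene AADACP1 from 0.681 to 7.65. The mitochondrial tRNAs MT-TV and MT-TF went from 21.8 to 166.5 and from 13.6 to 105 FPKM. PDE7B-AS1 rose from 1.06 to 25.5 FPKM, and as its strand setting is unknown its reads cannot be told from those of PDE7B. SCD fell from 257 ± 2.43 to 53.6 ± 0.918 FPKM (log2 -2.24, adjusted p = 9.61e-16), the fatty acid desaturase FADS1 from 47.8 to 10.6, DENND2A from 5.97 to 0.609 and AFAP1L2 from 8.72 to 1.34. HNRNPA1L2 (33.3 to 0.936 FPKM, adjusted p = 0.00111), the small Cajal body RNA SCARNA22 (8.40 to 0.111 FPKM, adjusted p = 0.0121) and UBE2V2 (log2 -1.96, adjusted p = 0.0052) also fell, the last from uneven wild-type libraries of 12.6, 36.9 and 32.4 FPKM. SCARNA22 was uneven in other groups, at 11.03, 0.114 and 9.27 FPKM in untreated knockout cells. In wild-type cells under olaparib it stood at 0.089, 7.19 and 7.16 FPKM, so its fall is uncertain.

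Cell cycle lists fell under siPARP1 in wild-type cells too. G2/M genes fell in 39 of 40, also adjusted over the list alone (median -0.92, camera adjusted p = 7.25e-24), TOP2A from 155 to 69.9 FPKM and the kinesin KIF11 by 1.24, the latter lost with transcript sums (adjusted p = 0.266). G1/S genes fell in 32 of 37 (33 adjusted over the list alone, adjusted p = 4.14e-13) and DNA repair genes in 19 of 37, with 5 risen, also adjusted over the list alone (adjusted p = 0.00107), FANCD2 by 1.10 and the polymerase POLQ by 0.71. Cholesterol synthesis fell in 19 of 24 and rose in 1, also adjusted over the list alone (adjusted p = 9.34e-08), HMGCS1 from 44.0 to 19.3 FPKM. Integrated stress response genes fell in 18 of 31 and rose in 5 (19 and 6 adjusted over the list alone, adjusted p = 0.00092), DDIT4 by 1.45. Adhesion and migration genes fell in 15 of 33 and rose in 3, also adjusted over the list alone (median -0.19, adjusted p = 0.00102). The receptor kinase AXL fell from 129 to 70.8 FPKM, L1CAM from 123 to 51.4 and the integrin ITGB4 from 23.2 to 5.56 FPKM. Luminal markers fell in 5 of 8, also adjusted over the list alone (adjusted p = 0.00306, and adjusted p = 0.0695 with an estimated correlation), KRT18 from 1058 to 543 FPKM and KRT19 from 372 to 147 FPKM. Hypoxia genes fell in 14 of 32 and rose in 3, also adjusted over the list alone (adjusted p = 0.00549, and adjusted p = 0.0535 with an estimated correlation), LDHA from 384 to 195 FPKM, while SLC2A3 rose by 1.27. Histones rose in 8 of 14, also adjusted over the list alone (median 0.44, adjusted p = 0.00622, and adjusted p = 0.0538 with an estimated correlation), and mitochondrial transcripts in 12 of 13, also adjusted over the list alone (adjusted p = 0.000128, but adjusted p = 0.322 with an estimated correlation), MT-ND1 by 1.17. Mesenchymal markers fell in 11 of 23 and rose in 5, also adjusted over the list alone, without passing as a list (adjusted p = 0.104). Targets of p53 rose in 9 of 27 and fell in 6 (10 and 6 adjusted over the list alone), with a median of -0.013, a mean of 0.11 and an upward test (adjusted p = 0.683). Invasion proteases rose in 9 of 24 and fell in 9 (10 and 10 adjusted over the list alone), with a median of -0.022 and a mean of 0.067 and a downward test (adjusted p = 0.908). PARP family genes rose in 7 of 22 and fell in 7, also adjusted over the list alone, with a median of 0.084 and a mean of -0.053 and a downward test (adjusted p = 0.952). In all, 4649 genes were higher and 3508 lower, 444 and 391 by at least 2-fold. Higher genes were 57.0% of the calls, and a minority of 47.2% with median-of-ratios scaling. Transfection and time in culture cannot be separated from the knockdown, as no library with a non-targeting siRNA was analysed here.

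**Figure D3:**
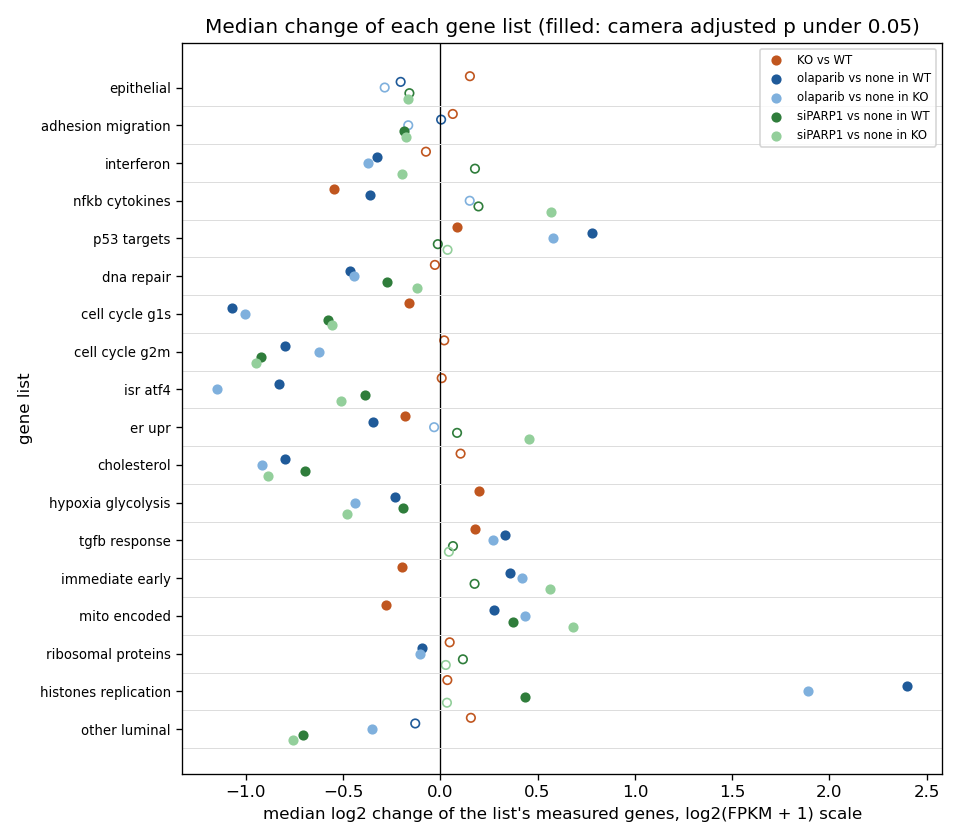
Median log2 change of 18 gene lists for knockout against wild type and for each treatment in each genotype (filled points, camera adjusted p under 0.05). Histones reach 2.40 under olaparib in wild-type cells and 0.44 under siPARP1, while G1/S genes reach -1.07 and -0.58.

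The treatments were then compared with no treatment in knockout cells. Under olaparib FOS rose from 1.33 to 57.4 FPKM (log2 4.65, SE 0.084, adjusted p = 2.7e-14), and H2BC11, H2AC18 and MIR137 rose by 3.35, 3.20 and 3.23. DDIT4 fell from 101 to 8.68 FPKM and CHAC1 from 15.5 to 0.919 FPKM, and JDP2 and LINC01583 fell by 2.89 and 2.67. JDP2 had libraries of a group up to 3.4-fold apart after 0.1 FPKM was added. Integrated stress response genes fell in 27 of 31 (median -1.15, adjusted p = 4.94e-17), G1/S genes in 31 of 37 (adjusted p = 2.56e-16) and hypoxia genes in 20 of 32 (adjusted p = 2.68e-06), and p53 targets rose in 21 of 27 (adjusted p = 1.17e-09), with the same counts adjusted over the list alone except for hypoxia genes (21). NF-kB targets rose in 10 of 25 and fell in 6, also adjusted over the list alone, without passing (adjusted p = 0.231). Calls for mitochondrial transcripts (13 of 13 rose), ribosomal proteins (25 of 73 fell, 24 adjusted over the list alone) and luminal markers (4 of 8 fell) were lost with an estimated correlation (adjusted p = 0.2, 0.316 and 0.0779). The genes changed numbered 3974 higher and 3469 lower, 53.4% higher, and 49.2% with median-of-ratios scaling.

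With siPARP1 in knockout cells, ANKRD1 rose from 62.2 to 613 FPKM (log2 3.28, SE 0.034) and CXCL8 from 1.35 to 14.98 FPKM (log2 2.77), while SCD fell from 291 to 45.4 FPKM and MGARP from 13.9 to 1.11 FPKM. PDE7B-AS1 rose by 4.25. Of the small nucleolar RNAs, which lie in introns of host genes, SNORD30 rose (log2 3.38, SE 1.07, adjusted p = 0.015) and SNORD58B fell (log2 -5.15, SE 1.58, adjusted p = 0.0127). SNORD58B and the pseudogene LDHAP4 (log2 -2.65) had siPARP1 libraries at least 3-fold apart. SNORD30 was uneven too, with libraries of a group up to 79.5-fold apart after 0.1 FPKM was added, so its rise is also uncertain. G2/M genes fell in 39 of 40 (adjusted p = 4.51e-23) and interferon-stimulated genes in 14 of 33 with 3 risen (adjusted p = 0.00192). NF-kB targets rose in 17 of 25 and fell in 4 (adjusted p = 0.00103), and ER stress genes rose in 17 of 26 and fell in 3 (adjusted p = 0.00139), and counts adjusted over the list alone were the same for these lists. The mitochondrial call (13 of 13 rose) gave an adjusted p = 0.139 with an estimated correlation, and that of epithelial markers (6 of 13 fell, 3 rose, adjusted p = 0.0439) an adjusted p = 0.198. The epithelial call also ended with median-of-ratios scaling (adjusted p = 0.057), without knockout library 2 (adjusted p = 0.0509) and without siPARP1 library 2 (adjusted p = 0.0532). In all, 5034 genes were higher and 3588 lower, 58.4% higher, and 48.4% with median-of-ratios scaling, so that the majority turns.

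Knockout and wild type were also compared under each treatment. Under olaparib, UCHL1 (log2 -5.07), LNCAROD (log2 -5.07) and SERPINB2 (log2 -3.32) were lower in knockout cells, as was the quinone reductase NQO1, from 8.13 to 0.069 FPKM. EPB41L4B rose from 7.91 to 20.6 FPKM, filaggrin, FLG, from 10.4 to 26.4 and caldesmon, CALD1, from 9.87 to 23.9 FPKM. COX7A2L rose by 1.53 (SE 0.406, adjusted p = 0.0227), but the call was lost without any of 5 of the 6 libraries. NF-kB targets were lower in 9 of 25 and higher in 2 (12 and 3 adjusted over the list alone, adjusted p = 2e-04) and interferon-stimulated genes lower in 11 of 33 and higher in 1 (15 and 1 adjusted over the list alone, adjusted p = 6.1e-05). G2/M genes were higher in 13 of 40 (17, and 1 lower, adjusted over the list alone, adjusted p = 5.21e-07). Immediate early genes were lower in 8 of 25 and higher in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.00703), a call lost with an estimated correlation (adjusted p = 0.0507) and with bin medians removed (adjusted p = 0.0529). In all, 895 genes were higher and 1128 lower, 44.2% higher, and 58.6% higher after rescaling to TPM or 52.6% with median-of-ratios scaling.

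Under siPARP1, UCHL1 stood at 65.1 FPKM in wild-type cells and was listed at 0, 0 and 0 in knockout cells, as was SNRPN. SERPINB2 was 161 FPKM in wild-type and 1.49 FPKM in knockout cells, and LNCAROD was lower by a log2 of -5.10. RGS4, a regulator of G protein signalling, rose from 21.4 to 62.5 FPKM, the actin-binding TAGLN from 6.14 to 18.6 and the nuclear receptor PPARG, in the chromosome 3 segment that was higher in knockout cells, from 4.46 to 12.9. MIR137 was higher in knockout cells (log2 2.14), with wild-type libraries at 0.108, 2.94 and 0.127 FPKM. Interferon-stimulated genes were lower in 23 of 33 and higher in none (26 lower adjusted over the list alone, median -0.47, adjusted p = 1.97e-15). Among them, chosen after their values were seen, IFIT1 measured 6.64 and 2.37 FPKM, and IFIT3 10.3 and 3.90 FPKM, in wild-type and knockout cells. NF-kB targets were lower in 15 of 25 and higher in 3 (17 and 3 adjusted over the list alone, adjusted p = 3.18e-09), and histones lower in 7 of 14, also adjusted over the list alone (adjusted p = 4.25e-05). G1/S genes were lower in 9 of 37 and higher in 1, also adjusted over the list alone (adjusted p = 0.00377), cholesterol synthesis lower in 10 of 24 and higher in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00378, and adjusted p = 0.0678 with an estimated correlation), and ER stress genes higher in 10 of 26, also adjusted over the list alone (adjusted p = 0.0083). The genes numbered 1863 higher and 1771 lower, 51.3% higher, and 61.4% after rescaling to TPM or 62.4% when scaled on protein-coding genes, but 49.1% with median-of-ratios scaling.

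Interactions tested whether a treatment acted differently in the 2 genotypes. Both interactions subtract the same untreated difference between knockout and wild type, so they share the untreated libraries and are not independent. A difference present only in untreated cells would appear in both. For olaparib, CXCL1 measured 43.4, 6.84, 34.5 and 27.5 FPKM in untreated wild-type and knockout cells and in treated wild-type and knockout cells (interaction log2 2.18, SE 0.059, adjusted p = 1.65e-11). In the same order CXCL8 measured 23.0, 1.35, 13.5 and 5.31 FPKM (2.15) and TIMP3 72.6, 3.54, 44.4 and 11.8 FPKM (2.19). PADI2 (-1.54) and CXorf38 (-1.52) had negative interactions. COX7A2L (2.69, adjusted p = 0.0199) and FOSL2 (-1.97, adjusted p = 0.0462) passed on uneven libraries, and FOSL2 stood at 9.46, 38.1 and 8.92 FPKM in knockout cells under olaparib. The FOSL2 call was lost in 11 of 12 fits that left out a library. NF-kB targets were positive in 10 of 25 (15, with 2 negative, adjusted over the list alone, median 0.42, adjusted p = 7.12e-13), ER stress genes positive in 6 of 26 (10 adjusted over the list alone, adjusted p = 1.18e-10) and hypoxia genes negative in 8 of 32 (10 adjusted over the list alone, adjusted p = 2.83e-08). In all, 221 interactions were positive and 261 negative, 45.9% positive, and 53.7% with median-of-ratios scaling.

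For siPARP1, CXCL1 measured 43.4, 6.84, 49.8 and 23.2 FPKM in the same order of groups (interaction log2 1.43, SE 0.059, adjusted p = 5.73e-09). The chaperone HSPA8 measured 709, 310, 900.2 and 1114 FPKM (1.52, adjusted p = 0.000401), and RPE 25.2, 43.9, 29.4 and 11.03 FPKM (-2.07, adjusted p = 0.000575). SERPINB2 measured 11.8, 0.149, 161 and 1.49 FPKM (-2.52, adjusted p = 4.46e-05), and with a pseudocount of 0.1 its interaction was -1.02 and did not pass (adjusted p = 0.218). AADAC was listed at 0, 0 and 0 in untreated knockout cells and reached 9.10 and 0.275 FPKM in treated wild-type and knockout cells. MIR137 (2.10, adjusted p = 0.0186), SLC33A1 (1.65, adjusted p = 0.0417) and SNHG26 (-1.98, adjusted p = 0.0385) passed with little margin. MIR137 did not pass with a pseudocount of 0.1 (adjusted p = 0.0626), and SLC33A1 and SNHG26 were lost in 10 and 9 of 12 fits that left out a library. Interferon-stimulated genes were negative in 10 of 33 (19 adjusted over the list alone, median -0.36, adjusted p = 3.06e-13), ER stress genes positive in 10 of 26 (16 adjusted over the list alone, adjusted p = 5.2e-13), hypoxia genes negative in 11 of 32 (12, with 1 positive, adjusted over the list alone, adjusted p = 1.63e-09) and histones negative in 6 of 14 (7 adjusted over the list alone, adjusted p = 1.94e-07). In all, 432 interactions were positive and 397 negative, 52.1% positive, 69.3% when scaled on protein-coding genes and 47.3% with median-of-ratios scaling.

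Responses to the 2 treatments were set side by side in wild-type cells. SCD, TOP2A and the cell cycle lists fell under both, while histones rose by a median of 2.40 under olaparib and 0.44 under siPARP1. The histone call under siPARP1 was lost in camera with an estimated correlation (adjusted p = 0.0538). Both treatments moved 2078 genes up and 1592 down, where independent lists would share 1159.6 and 716.3 (the product of the calls divided by the genes tested), and 1016 genes went opposite ways, against 1824.3. The correlation of log2 changes across genes, which are not independent replicates, was 0.426, and 0.5 in simulated unchanged groups that share the 3 controls. The covariance was 0.108, against 0.0163 in the simulation. The simulated overlap of calls was 0, but unchanged groups leave hardly any genes to call. It therefore does not measure what shared controls add to the real overlap. The 3 controls cannot be split, so part of the excess may come from the shared libraries, but siPARP1 in wild-type and olaparib in knockout cells, which share none, still gave a covariance of 0.0947 and a correlation of 0.362. Each treatment acted on many of the same genes in both genotypes, with 5394 genes changed in the same direction by olaparib and 57 in opposite directions (correlation 0.806), and 6474 and 54 for siPARP1 (correlation 0.811), with no shared library. Knockout and olaparib moved 1069 genes the same way and 912 opposite ways in wild-type background, with a covariance of 0.0162, against 0.0164 simulated. Of the former, 494 rose and 575 fell in both, where independent lists would share 376.6 and 350.6, and 736.6 would go opposite ways. Both directions thus exceeded independence. Knockout and siPARP1 moved 823 genes the same way and 1362 opposite ways, with a covariance of -0.00784, against 0.0163 simulated. Here 354 rose and 469 fell in both, against 445.3 and 382.1 for independent lists, and 842.4 were expected to go opposite ways.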

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

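In this part, leaving out single libraries for the lists and the sorting of the splits by turned treatment labels were chosen only after the results were seen. Each value below is the log2 difference between knockout and wild-type cells in the response to a treatment, and each was tested as an interaction in limma or camera. The olaparib and siPARP1 interactions share the untreated libraries, so genes or lists with the same sign in both are not independent results. Groups of 3 libraries were too small to be tested for single outlying samples.

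The response to olaparib differed between the genotypes for 482 genes. It was more positive in knockout cells for COX7A2L (2.69), TIMP3 (2.19), CXCL1 (2.18) and CXCL8 (2.15), and more negative for FOSL2 (-1.97), PADI2 (-1.54) and CXorf38 (-1.52). COX7A2L lost its call without any of 4 of 12 libraries, wild-type libraries 1 and 2 and wild-type olaparib libraries 1 and 2 (adjusted p = 0.0513 to 0.0537). By list, the median difference was 0.42 for NF-kB targets, 0.21 for ER stress genes, 0.16 for G2/M genes, 0.15 for G1/S genes and 0.16 for mitochondrial transcripts. It was -0.19 for hypoxia genes, -0.22 for the integrated stress response, -0.16 for the PARP family, -0.29 for histones, -0.18 for cholesterol synthesis, -0.11 for mesenchymal markers and -0.21 for luminal markers. With an estimated correlation 7 of these 12 lists still passed, and those that did not were mitochondrial transcripts (adjusted p = 0.211), histones (adjusted p = 0.0568), cholesterol synthesis (adjusted p = 0.0809), mesenchymal markers (adjusted p = 0.0809) and luminal markers (adjusted p = 0.115). Cholesterol synthesis was also lost without wild-type library 1 (adjusted p = 0.0569), mesenchymal markers without wild-type olaparib library 1 (adjusted p = 0.0573), and luminal markers without wild-type library 3 (adjusted p = 0.056), knockout library 2 (adjusted p = 0.0585), wild-type olaparib library 2 (adjusted p = 0.0718) or knockout olaparib library 3 (adjusted p = 0.0572).

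The response to siPARP1 differed for 829 genes. It was more positive in knockout cells for MIR137 (2.10), SLC33A1 (1.65), HSPA8 (1.52) and CXCL1 (1.43), and more negative for SERPINB2 (-2.52), AADAC (-2.35), RPE (-2.07) and SNHG26 (-1.98). By list, the median difference was 0.34 for ER stress genes, 0.30 for mitochondrial transcripts, 0.23 for NF-kB targets and 0.23 for immediate early genes. It was -0.36 for interferon-stimulated genes, -0.30 for hypoxia genes, -0.39 for histones, -0.22 for cholesterol synthesis, -0.17 for the PARP family, -0.12 for the integrated stress response and -0.063 for ribosomal proteins. The calls for mitochondrial transcripts (adjusted p = 0.121) and ribosomal proteins (adjusted p = 0.386) were lost with an estimated correlation, and that for ribosomal proteins also without wild-type library 3 (adjusted p = 0.0643) or knockout library 2 (adjusted p = 0.051).

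For each interaction, 11 of 100 splits of the libraries, the real one included, called at least as many genes as the real 482 or 829, so the count of splits does not exclude chance. The highest of the others called 4198 genes for olaparib and 5787 for siPARP1, several times the real counts, which points to a structure of the samples. All 10 of the larger splits had the treatment labels turned in 1 genotype and so measured the treatments themselves, and among the 49 that did not, the highest called 59 and 177 genes. Those 49 mix treated and untreated libraries within a group, so the treatment effect widens their spread. Few calls in them were therefore built in, and they do not bear out the real 482 or 829.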

How the results depend on the processing

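Scaling on protein-coding genes, leaving out assembled loci, removing the medians of 10 Mb bins, and leaving out libraries for lists and overlaps were alternatives chosen after the data had been seen. Counts of changed genes stayed within 1.5 times the reported count in 163 of 168 alternatives, and the 66 overlaps in all. Levels of TRIM27, PARP1 and PAX6 kept their side of the threshold in 445 of 468 (20 weaker, 3 stronger), and no change that passed turned direction. Changes that did not pass could switch sign and still count as kept. TRIM27 under olaparib in wild-type cells, for instance, ran from -0.109 to 0.032 without single libraries. Of 3908 values for other named genes 68 were weaker and 2 reversed, and of 2736 for lists 40 were weaker and 37 stronger. A fit of only the groups compared, with fewer samples behind the spread, called 2144 genes for knockout against wild type, 2213 under siPARP1 and 500 for the siPARP1 interaction. With bin medians removed over all chromosomes, 1292 genes differed between knockout and wild type under olaparib, and in untreated knockout cells mesenchymal (median 0.24, adjusted p = 0.00618), epithelial (0.19, adjusted p = 0.0151), adhesion (0.10, adjusted p = 0.00744), integrated stress response (0.09, adjusted p = 0.00618) and luminal lists (0.26, adjusted p = 0.0158) passed. Without single libraries the olaparib interaction gave 313 to 399 genes, the lowest without wild-type library 1.

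The rise of TRIM27 under siPARP1 in wild-type cells was 0.26 without a filter (adjusted p = 0.0848), where more genes were tested, 0.21 with median-of-ratios scaling (adjusted p = 0.0904), 0.32 with protein-coding scaling (adjusted p = 0.0624) and 0.26 in the fit of its own groups (adjusted p = 0.156). It ran from 0.15 to 0.34 without single libraries, and that in knockout cells from 0.26 to 0.31. PARP1 from transcript sums changed by -0.96 (adjusted p = 0.109) and -0.22 (adjusted p = 0.733) under olaparib in wild-type and knockout cells and by -0.73 (adjusted p = 0.206) under siPARP1 in knockout cells. These sums miss most of the PARP1 gene value, as they held 14.3 of 56.2 FPKM in untreated wild-type cells. PARP1 under siPARP1 was lower in knockout than in wild-type cells with a pseudocount of 0.1 (-0.21, adjusted p = 0.0484) and with a filter at 5 FPKM (-0.19, adjusted p = 0.0494, fewer genes tested), and ran from -0.24 to -0.14 without single libraries. The rise of PAX6 in knockout cells was 1.15 with a pseudocount of 0.1 (adjusted p = 0.0926), 0.52 in the fit of its own groups (adjusted p = 0.0526) and 0.47 to 0.57 without single libraries. Its fall under siPARP1 in knockout cells was -0.93 (adjusted p = 0.0975), -0.43 (adjusted p = 0.0691) and -0.53 to -0.38 in the same order. HSPA5 reversed with transcript sums, to 1.499 in knockout cells (adjusted p = 0.657) and 0.91 under olaparib (adjusted p = 0.738). With an estimated correlation 5 of 8 lists passed for knockout against wild type, 6 of 10 for siPARP1 in wild-type cells and 7 of 12 for the olaparib interaction. Where no construction is named, the cause was not tested. TRIM27 and PAX6 have no value under the filter at 5 FPKM.

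Replicate numbers were not used as pairs in the main fit. The 45 same-numbered pairs of libraries from different groups correlated in their deviations at -0.071 to 0.087 (mean 0.007, other pairs -0.003), though 14 of 18 libraries correlated best with their own number, a hint from the data and not the design. With the replicate block the counts were 3119 for knockout against wild type, 7041 for olaparib and 8111 for siPARP1 in wild-type cells, 7365 and 8534 in knockout cells, 1900 and 3541 for knockout against wild type under olaparib and siPARP1, and 426 and 742 for the interactions. FOSL2 (adjusted p = 0.0573) and SNHG26 (adjusted p = 0.0565) no longer passed in their interactions with the block, and adhesion genes and luminal markers in knockout cells (adjusted p = 0.0492 for both) and mesenchymal markers under siPARP1 in knockout cells (adjusted p = 0.049) did. Depth was estimated only as a rough ratio between libraries, which limits low genes such as PAX6 and TRIM27.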

Other observations

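In this part, the genes named in the next paragraph were chosen after their values were seen, and so were the tests of the chromosome segments, of TRIM27 loss as their source, of the histone reads and of the region around TRIM27, and the count of genes that the GC and length trend moved. The splits of the samples and the tests of GC content, gene length and RNAs without a tail were fixed beforehand.

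Smooth muscle actin, ACTA2, rose from 20.2 to 113 FPKM under olaparib in wild-type cells (limma adjusted p = 5.84e-13) and from 19.7 to 104 FPKM in knockout cells (adjusted p = 7.01e-13), while under siPARP1 it was 16.8 and 19.8 FPKM. TAGLN rose under siPARP1, from 1.64 to 6.14 FPKM in wild-type (adjusted p = 5.06e-08) and from 2.29 to 18.6 FPKM in knockout cells (adjusted p = 8.02e-11). The collagen cross-linking oxidase LOX fell under olaparib from 66.5 to 19.5 FPKM in wild-type and from 89.1 to 22.9 FPKM in knockout cells, and rose under siPARP1 to 78.3 and 114 FPKM. The plasminogen activator PLAT fell under both treatments in wild-type cells, from 249.5 to 73.7 and 114 FPKM. The cathepsin CTSL rose under siPARP1 from 31.2 to 83.3 FPKM in wild-type cells (adjusted p = 4.73e-09) and from 29.2 to 56.8 FPKM in knockout cells, a smaller rise in the latter (interaction adjusted p = 0.0392). WASHC2A and WASHC2C, near-identical copies that share reads, rose under siPARP1 in wild-type cells by 1.46 and 1.44. IL6 fell from 15.8 to 5.51 FPKM in knockout cells (adjusted p = 6.53e-09) and stood at 17.97 FPKM in the same cells under olaparib. SAMD9L fell from 4.19 to 0.19 FPKM in knockout cells (adjusted p = 9.88e-09). IL6 and SAMD9L lie in segments of chromosome 7 with medians of -0.29 and -0.18 in knockout cells.

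Differences between knockout and wild type ran along chromosomes. Neighbouring bins of 10 Mb correlated in their median change at 0.767 (257 bins, 8145 genes, shuffled 95th percentile 0.115, highest shuffled value 0.259). In all, 8 segments moved as a whole, for example the first 60 Mb of chromosome 3 by 0.30 in 230 genes, 92.6% of them of the same sign. A copy number difference between knockout and wild-type cells could give this, but a correlation above the shuffled 95th percentile does not by itself show it. Olaparib gave much weaker correlations of 0.204 in wild-type and 0.173 in knockout cells, over their shuffled 95th percentiles of 0.106 and 0.119. Unlike the knockout value, these lay under the highest shuffled values, 0.247 and 0.214 (siPARP1 gave 0.026 and -0.014). GC content and gene length are argued against as the whole source, since removing their trend, which moved 1191 of 8142 genes by at least 0.05 and ran from -0.055 to 0.056 between its 5th and 95th percentiles, left the correlation at 0.767 (0.7672 before and 0.7666 after). Loss of TRIM27 itself cannot be told apart, because the bins correlated at 0.884 between untreated and olaparib-treated cells, as they would with either source. The labels do not say whether the knockout libraries came from 1 clone or population or from several.

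Histones rose 2.40 in median under olaparib in wild-type cells, in libraries primed on poly(A). More capture of RNAs without a tail is argued against as the whole source, since other such RNAs had a median of -0.027 with an interval from -1.04 to 0.51, under the 1.2 that the explanation needs, though only 8 of 22 were measured. Mitochondrial tRNAs rose by 1.09 and small nucleolar RNAs by 0.27 under olaparib, which goes with that explanation, yet they rose by 1.27 and 0.49 under siPARP1, where the histone median was 0.44. That histone call was lost in camera with an estimated correlation (adjusted p = 0.0538). Reads moving among the 14 measured histones of the list are argued against, since their summed FPKM was 5.08 times higher in the lowest olaparib library than in the highest untreated one. The sum leaves out other histone copies and the unnamed assembled loci, so it cannot tell whether reads were gained from those. Whether histone transcripts gained tails or amount stays open.

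TRIM27 was low even in wild-type cells, and it lies beside the major histocompatibility region. Of 836 other windows of 6 Mb, 0% had a median as low as the 1.381 FPKM of 114 genes between 28 and 34 Mb of chromosome 6 (means over the 18 libraries), and HLA-C stood at 0.41 and HLA-B at 1.75 FPKM beside 245.48 for B2M. Reads of that region that went uncounted, as would happen if they also matched alternate sequences of it, may therefore hold down the TRIM27 values. The region's own gene content stays open, since windows differ in which genes they hold.

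Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. All splits but the real one mix both kinds of library within a group, so a real difference widens their spread. Low counts in them are partly built in and do not measure false calls. In 1 of 10, the real one, as many genes were called for knockout against wild type (3227, highest other 1), olaparib in wild-type cells (7151, highest other 3), siPARP1 in wild-type cells (8157, highest other 3), olaparib in knockout cells (7443, highest other 2), siPARP1 in knockout cells (8622, highest other 2), and knockout against wild type under olaparib (2023, highest other 2) and siPARP1 (3634, highest other 3).

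Uneven libraries lie behind several named genes. Among genes with a mean of at least 5 FPKM, 374 of 9785 (3.8%) had libraries of a group at least 3-fold apart, and so had 14 of the 162 named genes, TOMM6, HNRNPA1L2, COX7A2L and FOSL2 among them.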
